A study of Mus musculus with 6 samples.

How the data were processed

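RNA was measured in type II alveolar epithelial cells isolated from the lungs of 2-month-old mice. Each of the 6 arrays held 1 pool of total RNA. There were 3 independent pools for each of the 2 genotypes per the series' design text, so p-values of single genes measure the spread between pools. The number of mice in a pool is not given in the sources used here. The target was biotin-labelled and hybridised to an Affymetrix array, per the labels' protocols. The deposited values are probe set signal intensities on a linear scale, and MAS5 made them per the submitters' processing notes, which give no version. As the deposited values show, each array had been scaled to the same trimmed mean of 1500 (mean of the values between the 2nd and the 98th percentile). Array medians lay between 426 and 479, a gap of 0.17 on the log2 scale. MAS5 treats each array alone, so differences of shape between arrays stay in the values, and it gives dim probe sets a noisy log ratio. Detection calls and saturation flags were not used here.

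The table held 45101 probe sets. Of these 64 were controls, 34945 named 1 gene, 932 named several and 9160 had no gene name here. Gene names came from the platform annotation, and 34754 of its probe sets with 1 gene, controls included, had an Entrez number found in a mouse gene table of assembly GRCm38.p6, where 0 symbols differed. Signals under 1 were set to 1 and log2 was taken. The values were used without further normalization because array medians lay within 0.2 on the log2 scale. Probe sets whose mean log2 signal lay below the 40th percentile of all non-control probe sets (log2 8.08, signal 271) were left out, which kept 27022. Each gene was represented by its brightest probe set naming that gene alone, which gave 12952 genes. The number of arrays limits the precision.

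Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. A log2 fold change is deleted minus control, given with its moderated standard error, and signals are given as mean ± SD over 3 pools. With 3 pools against 3, the smallest p of an exact two-sided permutation test is 0.1, so single genes were tested with limma alone. Before the data were examined, 28 gene lists were fixed for lipid metabolism, type II cell function, stress, inflammation, other lung cell types, sex and circadian time. The 25 lists with at least 5 genes tested went through camera with a preset correlation of 0.01, adjusted over those lists. Camera asks whether a list's genes moved more than other genes. With the preset correlation its p-value sets genes against genes, so it is no measure of the spread between pools. The correlation estimated from the data was higher for some lists, at 0.57 for cholesterol synthesis. Camera with an estimated correlation, camera on ranks, and fry, which asks whether a list's genes move one way without comparing them with other genes, were alternatives. Of the lists' members, 37 lay below the filter, 35 had no named probe set here and 6 had only probe sets naming several genes, so they were not analysed here.

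The genes named were set by a rule fixed before the data were examined. It took Insig1 and Insig2; the 10 largest increases and 10 largest decreases among genes past the threshold whose groups did not overlap, or the 5 smallest p in a direction with fewer than 5; any member of the cholesterol, fatty acid and surfactant lists; and from each other list up to 4 members past the threshold with the smallest p, or 2 if none passed. Unnamed and RIKEN or Gm gene models counted in totals but were skipped in ranking. Genes named outside the rule are said to be so. The alternatives, also fixed before the data were examined, were quantile normalization, a shift to a common median, log2 of the value plus 16, no intensity trend, array weights, no filter, a filter at the 60th percentile, the pool number as a block, each pool left out in turn, other ways to summarise probe sets and other thresholds. The steps were tested on simulated data made from 12952 genes with these arrays' spread, with 50 genes changed at each size. The gene test recovered 14% of genes with a true log2 change of 0.5, 54% of those with 1, 80% of those with 1.5 and 94% of those with 2, and 4 of its 131 calls were false. In the same simulation camera called 2 lists besides the list that had been changed. The simulated genes varied independently and no pool stood apart, so these rates do not cover correlated genes or an outlying pool. Figures were drawn with matplotlib 3.10.9.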

Results

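Transcript levels were measured in isolates of alveolar type II cells, the lung epithelial cells that make surfactant. In one group Insig1 had been deleted by a Cre recombinase under a doxycycline-responsive SFTPC driver. The labels of both groups give doxycycline from embryonic day E6.5 to E12.5. In the control group the floxed Insig1 gene was intact, since these mice lacked a part of the Cre system. Both groups lacked Insig2. INSIG1 and INSIG2 hold the SCAP-SREBP complex in the endoplasmic reticulum, and SREBP transcription factors drive genes of sterol and fatty acid synthesis. The comparison asks how the transcriptome of type II cell isolates differs when Insig1 is lost as well. Only the deleted group had the complete Cre system, and no group had it with Insig1 intact. An effect of the Cre system itself therefore cannot be told apart from that of Insig1 loss. There were 3 pools of RNA per genotype. Correlations of log2 signals between arrays ran from 0.924 to 0.940 within groups and from 0.927 to 0.938 between groups, and no array duplicated another. Control replicate 3 stood apart, at -39.1 on the first principal component (35.7% of variance) where the other controls lay at -12.9 and 3.35 and the deleted pools between 12.3 and 18.7, and it had the lowest array weight (0.437). Probe sets of Y-linked genes lay below the filter on average over the 6 arrays, and Xist probe sets had log2 signals of 9.14 or more on each of them.

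The Insig1 probe set had a signal of 1482 ± 251 in deleted pools and 2862 ± 519.5 in control pools (n = 3 each), a log2 fold change of -0.95 ± 0.18 (SE). Every deleted pool lay below every control pool, but the adjusted p of 0.068 (limma) missed the threshold. Whether this probe set lies inside the deleted part of the gene is not given in the sources used here, so it is no full check of the genotype labels, and Insig1 is itself an SREBP target. Insig2 had 3 probe sets, with log2 fold changes of -0.17, -0.23 and -0.26, and the brightest did not differ between groups by limma (adjusted p = 0.73). Signal from Insig2 probe sets in mice labelled as lacking the gene (2249 ± 392 in controls on the brightest) shows a level but not an intact transcript.

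Isolates of Insig1-deleted type II cells had 81 genes higher and 3 lower than control isolates, 84 of the 12952 genes tested. Markers of macrophages and airway cells were measured in these isolates too, so a higher gene need not have risen in type II cells. The largest increase was that of Slc26a4, an anion exchanger, which was 13.7-fold higher (16864 ± 3352 against 1364 ± 828, log2 3.77 ± 0.34, adjusted p = 0.0037). It was followed by Noxo1, a subunit of an NADPH oxidase (log2 3.15), Fgg, the fibrinogen gamma chain (2.35), Wfdc17 (2.34), Ccdc25 (2.27), the macrophage scavenger receptor gene Marco (2.26), H2-Q10 (2.25), the sterol enzyme gene Lss (2.22), Retnla, which encodes a resistin-like protein (2.15), and the IgE receptor gene Fcer2a (2.13). The 3 lower genes were Ccdc153 (log2 -1.18 ± 0.16), the transcription factor gene Sox2 (-0.83 ± 0.13) and Cdkn1c, a cell cycle inhibitor gene (-0.80 ± 0.13). Among decreases the next smallest p values belonged to Calml4 (log2 -0.90, adjusted p = 0.066) and Insig1, neither of which passed.

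Of the 84 genes, 62 changed at least 2-fold, and all 84 had groups that did not overlap, which 17.1% of all tested genes had and chance alone gives for 10%. At an unadjusted p under 0.05 there were 784 genes higher and 780 lower. Control signals of Fgg (249), H2-Q10 (241) and Ccdc25 (291) lay near the filter, where folds are least certain. The fold of Noxo1 was uncertain too, with a control signal of 428 ± 269.7 and a log2 fold change of 2.41 without control replicate 3. Without deleted replicate 1, 2 or 3 its adjusted p was 0.14, 0.16 and 0.15, and Fgg, H2-Q10 and Ccdc25 also missed the threshold in each of these fits. The count depended on single pools. It was 46 without control replicate 1, 477 without control replicate 2 (184 higher, 293 lower), 171 without control replicate 3, and 23, 15 and 31 without deleted replicates 1, 2 and 3. All 84 genes kept their direction in each of these fits, and 15 stayed past the threshold in all 6, among them Slc26a4, Lss, Sqle, Fdps, Msmo1, Aacs, Lpin1, Wfdc17, Retnla, Fcer2a, Gpnmb and Ccl6. Without an intensity trend 29 genes passed, and with array weights 259 (186 higher, 73 lower).

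**Figure D1:**
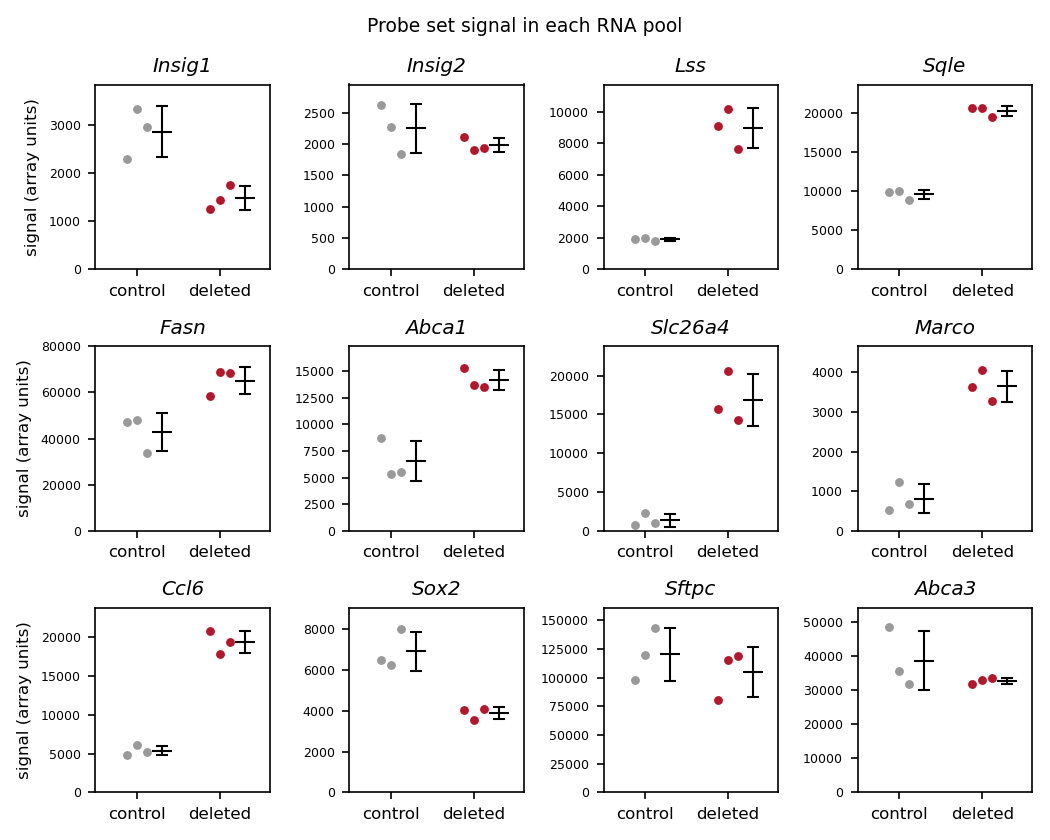
Signal of 12 probe sets in each pool of control and Insig1-deleted type II cells. The vertical axis is the linear array signal, each point is 1 pool (n = 3 per group) and the bar beside the points is the mean ± SD: Lss signals were 8983 ± 1258 in deleted pools and 1914 ± 92.0 in controls, while the ranges of Sftpc overlap.

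Cholesterol synthesis enzymes rose together. Of 18 measured genes 15 rose and none fell over all genes tested, and 16 rose when adjusted over the list alone. Lss, which encodes lanosterol synthase, rose 4.67-fold (log2 2.22 ± 0.13), Dhcr7, the last step of the pathway, 3.79-fold (1.92 ± 0.22), Mvd 3.58-fold (1.84 ± 0.24) and Fdps 3.27-fold (1.71 ± 0.16). Sqle, the gene of squalene epoxidase, went from 9624 ± 574 to 20328 ± 629 (log2 1.080 ± 0.101). Idi1, Cyp51, Tm7sf2, Nsdhl, Hsd17b7, Msmo1, Hmgcs1, Sc5d, Fdft1 and Pmvk also rose, by between log2 0.996 (Hmgcs1) and 1.61 (Tm7sf2). Other probe sets gave 1.84 and 1.54 for Lss, 0.48 for Mvk, 0.90 and 0.01 for Sc5d, 1.46 and 0.70 for Cyp51, and between 0.17 and 1.42 for Hmgcs1. Mvk had a log2 fold change of 1.080 with an adjusted p of 0.083, and the values of Ggps1 (-0.20) and Ebp (-0.11) did not pass. The list's median log2 fold change was 1.30 (camera adjusted p = 1.7e-28, adjusted p = 0.14 with an estimated correlation). Macrophage markers moved with it (median log2 0.90).

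The list of cholesterol uptake and sterol sensing genes lay higher (median log2 0.29, camera adjusted p = 3.1e-04, adjusted p = 0.18 with an estimated correlation), with none of its 13 measured genes past the threshold over all genes by limma, 2 adjusted over the list alone and 5 at an unadjusted p under 0.05. The sterol carrier gene Stard4 had a log2 fold change of 1.39 (adjusted p = 0.053) and the lipoprotein receptor gene Scarb1 0.78. Dimmer probe sets gave 1.37 and 1.36 for Stard4, and 1.02 and 0.96 for Scarb1. Among targets of LXR, the nuclear receptor activated by oxysterols, 1 of 12 measured genes rose over all genes and 5 adjusted over the list alone (median 0.30, camera adjusted p = 0.003, adjusted p = 0.14 with an estimated correlation). It was Abca1, the cholesterol exporter, at 14169 ± 957 against 6547 ± 1886 (log2 1.15 ± 0.18). Its other probe sets gave 0.89 and 0.59. Macrophage markers moved with these groups (median log2 0.90).

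Fatty acid synthesis genes lay higher, with smaller changes than the cholesterol list on the brightest probe sets. Over all genes 3 of 24 measured genes rose, and 14 adjusted over the list alone. These 3 were Aacs, which activates acetoacetate for lipid synthesis (2.90-fold, log2 1.53 ± 0.16), the desaturase gene Fads2 (2.46-fold, 1.30 ± 0.20) and the acetyl-CoA synthetase gene Acss2 (1.59-fold, 0.67 ± 0.12). Fasn, the fatty acid synthase gene, had a log2 fold change of 0.62 ± 0.16, Acaca 0.78, Acly 0.51, Srebf1 0.69, Scd2 0.67, Fads1 0.74, Thrsp 1.40 and Acacb 1.22, none past the threshold over all genes. The list's median was 0.49 (camera adjusted p = 1.5e-13, adjusted p = 0.14 with an estimated correlation), while that of macrophage markers was 0.90. The probe sets of Scd1, which makes monounsaturated fatty acids, disagreed. The brightest, near the top of the array's range at 133123 in deleted and 128283 in control pools, gave 0.05 ± 0.14, and a dimmer one gave 1.32 ± 0.16.

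**Figure D2:**
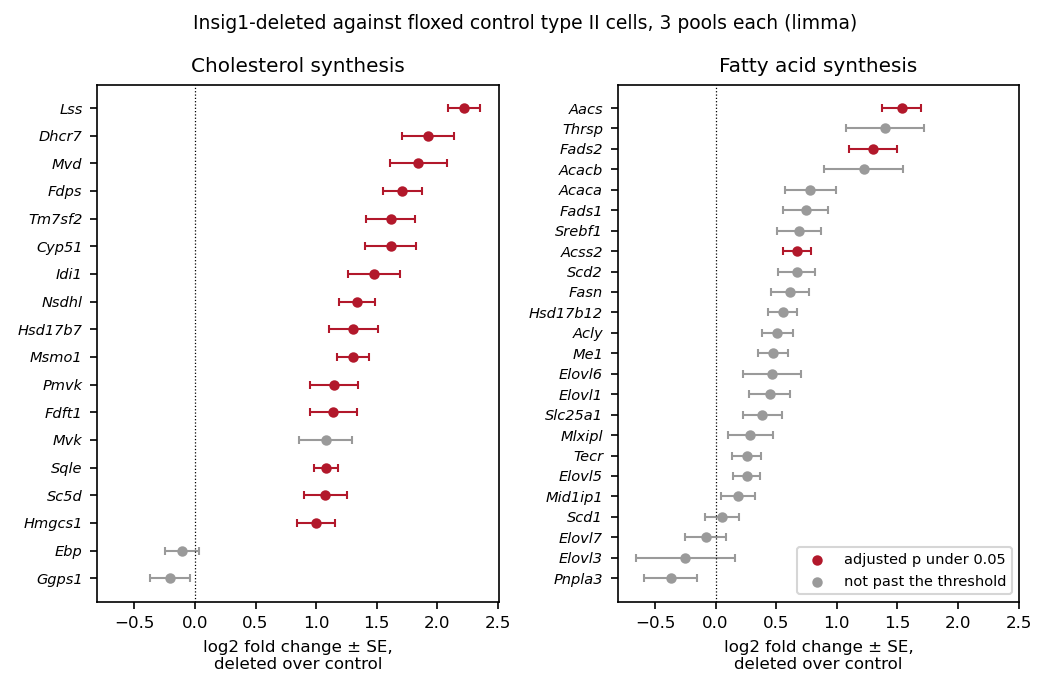
Log2 fold change with its standard error for each measured gene of cholesterol synthesis (left) and fatty acid synthesis (right), Insig1-deleted over control, 3 pools each. Red points passed an adjusted p of 0.05 over all genes (limma): 15 of 18 on the left, from Hmgcs1 at 0.996 to Lss at 2.22, and 3 of 24 on the right.

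The other lipid groups held single genes that rose. In the triglyceride and lipid droplet list 2 of 26 rose, over all genes and adjusted over the list alone. They were Lpin1, a phosphatidic acid phosphatase gene (2.50-fold, log2 1.32 ± 0.13), and Plin2, a lipid droplet coat gene (1.84-fold, 0.88 ± 0.12), while the list did not pass (median 0.05, camera adjusted p = 0.067). It passed without control replicate 1 (0.035) or deleted replicate 3 (0.017), with no filter (0.034) and with the filter at the 60th percentile (0.015). In phospholipid synthesis Lpcat3, which remodels phosphatidylcholine, rose 1.80-fold (0.85 ± 0.12), 1 of 22 over all genes and 2 adjusted over the list alone, and the list did not pass (median 0.05, camera adjusted p = 0.18). In fatty acid uptake and binding 1 of 12 rose on both counts, Fabp4 (2.10-fold, 1.07 ± 0.17), whose other probe sets gave 0.64 and 0.08. That list's median was -0.06 and its mean -0.04 while camera leaned upward (adjusted p = 0.78). None of 22 fatty acid oxidation genes passed on either count by limma, and 2 were higher at an unadjusted p under 0.05 (median 0.10, camera adjusted p = 0.077), where Eci1 had a log2 fold change of 0.79. That list passed without control replicate 2 (0.016) and with no filter (0.036).

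Surfactant and lamellar body genes were not found to differ. None of 17 measured genes passed by limma, over all genes or adjusted over the list alone, and 1 was higher at an unadjusted p under 0.05 (median log2 0.10, camera adjusted p = 0.14). The list passed without control replicate 2 (median 0.16, adjusted p = 0.025) or deleted replicate 1 (median 0.14, adjusted p = 0.042). Log2 fold changes were -0.20 ± 0.19 for Sftpc, 0.05 ± 0.14 for Sftpb, 0.03 ± 0.13 for Sftpa1, 0.23 ± 0.13 for Sftpd, -0.21 ± 0.15 for the lipid transporter gene Abca3 and 0.52 ± 0.16 for the protease gene Ctsh. The 4 surfactant protein probe sets had mean signals between 93759 and 138630 against array maxima of 141333 to 197205, so they lay close to the top of the range. None of 18 other type II cell markers passed on either count by limma, with 3 higher and 1 lower at an unadjusted p under 0.05 (median 0.11, camera adjusted p = 0.27), and that list passed without control replicate 2 (0.037). Fabp5, a fatty acid binding protein gene, stood at 0.57 ± 0.15 on its brightest probe set, which had a signal of 127056 in deleted pools, and at 1.30 ± 0.24 on a dimmer one.

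Markers of other cell types moved in both directions. Of 20 measured macrophage markers 7 rose over all genes and 16 adjusted over the list alone (median log2 0.90, camera adjusted p = 2.7e-21, adjusted p = 0.14 with an estimated correlation). Gpnmb rose 3.64-fold (3132 ± 23.2 against 877 ± 213), Marco 4.79-fold, Mpeg1 2.58-fold and Cd68 2.00-fold. Lymphocyte markers lay higher with none of 17 past the threshold over all genes by limma, 3 adjusted over the list alone and 4 at an unadjusted p under 0.05 (median 0.48, camera adjusted p = 8.4e-04, adjusted p = 0.51 with an estimated correlation), and Ccr7 stood at 1.27. That list missed the threshold without control replicate 1 (median 0.33, adjusted p = 0.064). Airway cell markers lay lower (median -0.34, camera adjusted p = 5.4e-05, adjusted p = 0.42 with an estimated correlation). Sox2 alone of 16 fell over all genes, and 3 fell adjusted over the list alone. Other splits of the pools gave smaller p-values than the genotypes for lymphocyte and airway markers.

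Type I cell markers (17 measured, median 0.04, camera adjusted p = 0.78), endothelial markers (18, median -0.10, 0.78), mesenchymal markers (20, median 0.04, 0.76) and mesothelial markers (5, median -0.41, 0.14) did not pass. Without control replicate 1 the mesothelial list passed (0.026), and without deleted replicate 1 the mesenchymal list did (0.016). The mesenchymal mean was -8.7e-04 while camera leaned upward. Among them the carbonic anhydrase gene Car4, of the endothelial list, rose 1.86-fold (log2 0.89 ± 0.14). Of 4 neutrophil markers none passed over all genes and 2 rose adjusted over the list alone, with S100a8 at 1.01, and 3 erythroid markers had a median of -0.42. Both lists were too short for camera.

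**Figure D3:**
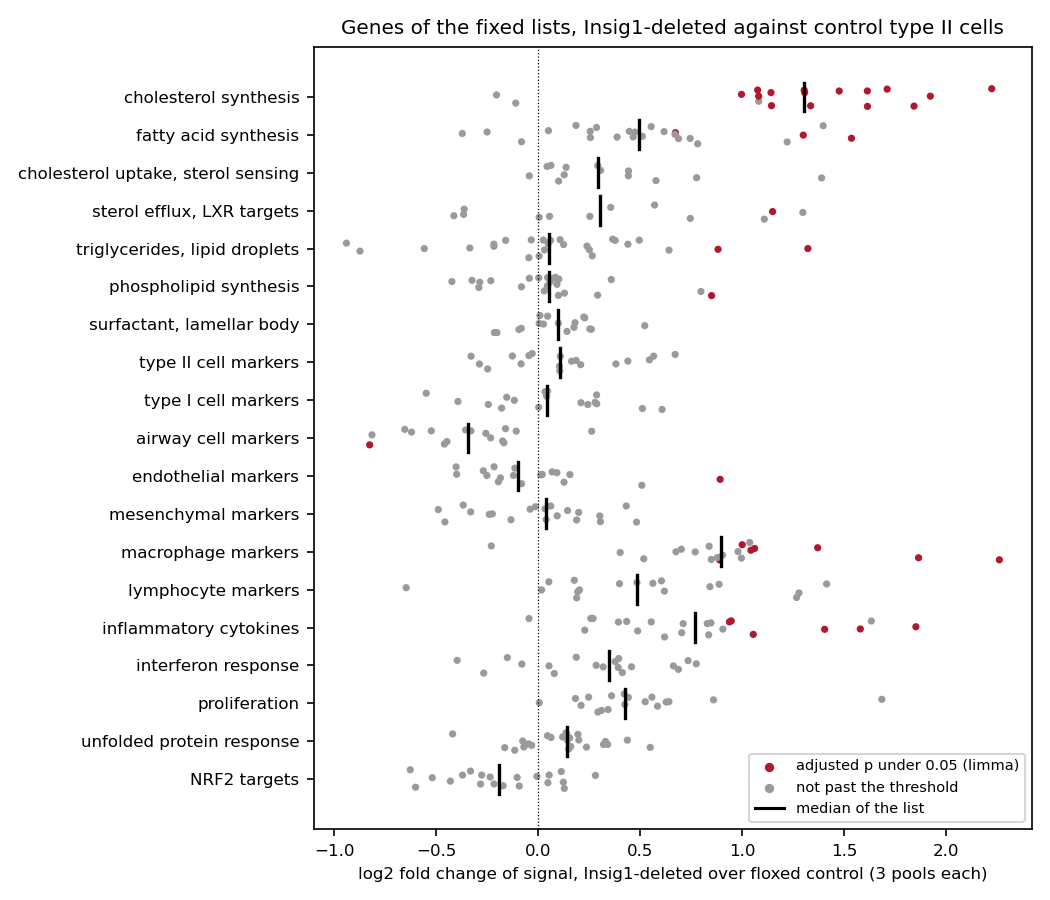
Log2 fold change (Insig1-deleted over control, horizontal axis) of every measured gene in 19 of the fixed lists, with the median of each list as a black line and genes past an adjusted p of 0.05 over all genes (limma) in red. Of the lists drawn, the medians of cholesterol synthesis (1.30) and macrophage markers (0.90) lie farthest to the right and that of airway cell markers (-0.34) farthest to the left.

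Inflammatory cytokine genes rose alongside the macrophage markers. Over all genes 6 of 22 rose, and 14 adjusted over the list alone (median log2 0.77, camera adjusted p = 2.5e-16, adjusted p = 0.14 with an estimated correlation). The chemokine gene Ccl6 rose 3.61-fold (19336 ± 1471 against 5373 ± 602), the siderophore-binding protein gene Lcn2 2.99-fold (70625 ± 7627 against 24969 ± 10370.5), and the chemokine genes Ccl9 2.65-fold and Cxcl5 2.08-fold. Interferon response genes lay higher with none of 18 past the threshold over all genes by limma, 1 adjusted over the list alone and 6 at an unadjusted p under 0.05 (median 0.35, camera adjusted p = 9.5e-04, adjusted p = 0.18 with an estimated correlation). The immunoproteasome gene Psmb8 stood at 0.77 with an adjusted p of 0.067.

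Proliferation genes lay higher as a list (median log2 0.42, camera adjusted p = 2.2e-06, adjusted p = 0.18 with an estimated correlation). All 18 had values above 0, none passed on either count by limma, 8 did at an unadjusted p under 0.05, and Mki67 stood at 0.86 and Cdc20 at 0.63. Macrophage (median 0.90) and lymphocyte markers (0.48) moved with this list. The unfolded protein response list lay slightly higher (24 genes, median 0.14, camera adjusted p = 0.018, adjusted p = 0.18 with an estimated correlation). None of its genes passed on either count by limma, with 2 higher and 1 lower at an unadjusted p under 0.05, and the brightest Hyou1 probe set gave 0.55 where another gave 0.00. That list missed the threshold without control replicate 1 (adjusted p = 0.067), with quantile normalization (0.059) and with the mean over probe sets (0.089). The NRF2 target list of antioxidant genes lay lower (20 genes, median -0.19, camera adjusted p = 0.036, adjusted p = 0.52 with an estimated correlation) with none past the threshold on either count by limma and 3 lower and 1 higher at an unadjusted p under 0.05. It missed the threshold without control replicate 3 (0.47) or deleted replicate 1 (0.26), without an intensity trend (0.064), with array weights (0.16) and with the mean over probe sets (0.27), and another split of the pools gave it a smaller p than the genotypes. Airway markers moved with this list (median -0.34). Gsr had a log2 fold change of -0.60 on its brightest probe set and 0.11 on another, and Gstm1 -0.52.

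Lists for apoptosis and p53 targets (median -0.08, camera adjusted p = 0.28), immediate early genes of cell isolation (0.04, 0.32) and the circadian clock (0.00, 0.63) did not pass, with none of 15, 22 and 16 genes past the threshold on either count by limma. At an unadjusted p under 0.05 the apoptosis list had 1 gene lower, the isolation list 3 higher and 1 lower, and the clock list 1 higher and 1 lower. The isolation list passed without control replicate 3 (0.014) or deleted replicate 1 (0.037) and with array weights (0.037), and another split of the pools gave it an adjusted p of 7.1e-08. The clock list's mean was -0.09 and its test pointed down. Hspa1a, a heat shock gene of the isolation list, had a log2 fold change of 0.42, and the clock gene Bhlhe40 0.35.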

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

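Probe sets that the gene-level comparison leaves out, because they name several genes or none here, were tested together with all 27022 probe sets past the filter. They drew attention because 4 of them were higher in Insig1-deleted pools than in control pools with adjusted p between 0.0061 and 0.028 (limma). The 2 that name several genes had log2 fold changes of 1.16 ± 0.17 (SE) and 1.39 ± 0.14. The brighter of them went from 13476 ± 2389 to 34959.7 ± 2718 (SD, limma, n = 3 each). The 2 with no gene name here had log2 fold changes of 1.34 ± 0.19 and 1.51 ± 0.20. No explanation was tested for these probe sets.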

How the results depend on the processing

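All 84 genes past the threshold kept their direction in each alternative that tested them. Quantile normalization gave 74 genes, of which 72 were among the 84, and the shift to a common median 113. Other counts moved by over 1.5 times. Without an intensity trend 29 genes passed (29 higher, 0 lower by limma); as reported, 780 genes were lower at an unadjusted p under 0.05. Array weights gave 259 (186 higher, 73 lower), the looser adjusted p of 0.10 gave 129 (11 lower), and an unadjusted p under 0.05 with a fold of at least 1.5 gave 708 (356 higher, 352 lower). With a pool left out the count ran from 15 to 477 (15 to 184 higher, 0 to 293 lower), and fewer pools were then tested. The cause of the other shifts was not tested.

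Insig1 had an adjusted p between 0.026 and 0.28 over its alternatives, with log2 fold changes from -1.10 to -0.81. It passed after a shift to a common median (-0.87, adjusted p = 0.049), with array weights (-0.81, adjusted p = 0.046) and with the replicate block (-0.95, adjusted p = 0.026). Insig2 ran from -0.31 to -0.05 and passed under none of its alternatives. The pool numbers were not found to pair the samples: deviations of same-numbered pools correlated at 0.074, 0.040 and 0.15, though each control pool correlated best with its own number. With the replicate block 132 genes passed (111 higher, 21 lower), and 83 of the 84 were among them.

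Of 12 lists past the threshold, camera with an estimated correlation kept 0, and fry, a different question, kept 5, namely cholesterol synthesis, fatty acid synthesis, LXR targets, cytokines and macrophage markers. Other settings gave 10 to 15 lists, and with the replicate block the mesothelial list passed (adjusted p = 0.049). Over their alternatives the adjusted p ran from 0.015 to 0.42 for the triglyceride list, 0.016 to 0.53 for fatty acid oxidation, 0.025 to 0.54 for surfactant, 0.037 to 0.80 for type II cell markers, 0.014 to 0.93 for the isolation list, 0.026 to 0.81 for mesothelial and 0.016 to 0.95 for mesenchymal markers. It ran from 0.011 to 0.52 for NRF2 targets, 0.0041 to 0.18 for the unfolded protein response, 6.5e-12 to 0.51 for lymphocyte markers and 2.5e-04 to 0.14 for LXR targets. List medians ran from -0.57 to -0.12 for airway markers, 0.26 to 0.98 for lymphocyte markers and 0.13 to 0.37 for cholesterol uptake and sterol sensing. On ranks the LXR targets (adjusted p = 0.057) and NRF2 targets (0.052) missed the threshold, and the fatty acid uptake list, at a median of -0.064, changed the test's direction. Type I cell markers (median 0.043) did so under quantile normalization, and Scgb1a1 turned with array weights (0.034). With a pool left out the test's direction turned in at least 1 fit for lists that did not pass as reported: type I cell markers (medians -0.046 to 0.17), mesenchymal markers (-0.14 to 0.25), type II cell markers (-0.020 to 0.24), endothelial markers (-0.16 to -0.033) and the clock (-0.0998 to 0.039). It also turned for Ebp (-0.23 to 0.012), Scd1 (-0.036 to 0.16), Sftpa1 (-0.051 to 0.091) and Sftpb (-0.019 to 0.16). Signals near the filter and near the top of the range limit the precision of folds.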

Other observations

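The genes named in the next 2 paragraphs outside the fixed rule, and the 6 added gene lists, were chosen after the gene results were seen. The added lists hold no gene past the threshold, so how many of their genes pass over all genes says nothing. Bootstrap intervals were made by resampling genes 10000 times and not pools. They treat genes as independent and do not measure the spread between pools. The tests that set macrophage markers against those of other cell types and bright against dimmer probe sets were also chosen after their values were seen, and so were the marker genes whose levels are given. Of the 84 genes past the threshold 46 belonged to none of the fixed lists. Several act in NF-kappaB signalling: Nfkbiz (log2 1.01 ± 0.11), Birc3 (1.03), Malt1 (1.11), Nfkbie (1.09), Nfkbid (0.96) and Tnfaip3 (0.82) were higher, and so were Tnfrsf9 (1.37), Cd83 (1.11) and Irf1 (0.59). Other probe sets gave 0.15 for Birc3, 0.66 and 0.21 for Nfkbiz, 0.81 and 0.44 for Malt1, 0.77 for Nfkbie and 1.23 for Tnfaip3. Macrophage markers moved with these genes (median 0.90). Among single genes Chil1 was at 85808 ± 2804 against 28040 ± 10714 (log2 1.69), Slpi at 1.57 and Lrg1 at 1.42, all higher. The complement genes C1qa (1.44) and C1qb (1.17), the beta-glucan receptor gene Clec7a (1.27), the metalloreductase gene Steap4 (1.70) and the retinol dehydrogenase gene Rdh11 (1.57) rose as well.

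Hypotheses on shared responses were tested on added lists that hold none of the genes that prompted them. Other NF-kappaB pathway genes lay higher (33 genes, median log2 0.23, bootstrap 95% interval 0.13 to 0.28, camera adjusted p = 0.0013 over 3 lists, adjusted p = 0.098 with an estimated correlation), though 0 passed by limma adjusted over the list alone (7 higher and 0 lower at an unadjusted p under 0.05). This is consistent with a rise of other pathway genes, whose size the left-out genes keep open. Other acute-phase and STAT3-induced genes, suggested by Lcn2, Lrg1 and Fgg, also lay higher (21 genes, 1 of them in a fixed list, median 0.28, interval 0.04 to 0.45, camera adjusted p = 0.0084, adjusted p = 0.098 with an estimated correlation). Here too 0 passed by limma adjusted over the list alone (7 higher and 3 lower at an unadjusted p under 0.05), with 16 values above and 5 below 0. The 3 lower genes were Cp (-0.58), also in the added club cell list, and the receptor genes Il1r1 (-0.55) and Il6ra (-0.47). Without control replicate 2 Il1r1 stood at -0.74 and was past the threshold. Macrophage markers moved with both lists (median 0.90 in the fixed list and 0.46 in the added myeloid list). For genes that IL-4 and IL-13 induce, suggested by Slc26a4, Retnla and Fcer2a, the test left the matter open. Camera gave an adjusted p of 0.017 (0.098 with an estimated correlation), but the median of 17 genes was 0.04 with an interval from -0.34 to 0.47, and 10 lay above and 7 below 0. This met both the condition set in advance for a shared rise, the camera p, and the one set against it, a median under 0.1 with an interval including 0. The second was judged a poor condition only after the result was seen, since members going both ways, with 5 of them higher adjusted over the list alone, exclude no rise of some. Which cells carry these transcripts cannot be read from pooled RNA.

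Macrophage markers were higher in the deleted isolates. A lower share of type II cells is argued against as the whole cause only if it would raise all other cell types alike, which is assumed here. Yet the median of endothelial, mesenchymal, type I and airway markers minus that of the macrophage list was -1.01 (bootstrap interval -1.16 to -0.83). These medians were known when the comparison was chosen, so it restates them and is no independent test. The airway list in it lay lower by itself (-0.34), and type II cells may express some of its club cell genes. Endothelial (-0.10) and mesenchymal (0.04) medians lay near 0. Over the alternatives the macrophage median ran from 0.80 to 0.99. Endothelial medians ran from -0.16 to -0.02, mesenchymal from -0.14 to 0.25 and type I from -0.05 to 0.17. More macrophages in the isolates may account for part of it, since 41 other myeloid genes, none in the fixed list, had a median of 0.46 (interval 0.40 to 0.64), with 16 higher adjusted over the list alone (list p = 0.0501 with an estimated correlation). A rise within macrophages or other cells stays open, as does the genotype itself, which was not tested apart. Signals of Chil3 (57440 against 28030), Ctss (17862 against 9497) and Cd14 (15315 against 7279) had higher means in deleted than in control pools, while Lgals3, which may also come from epithelium, had 48709 against 57969.5.

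The airway list lay lower, with 1 of 16 genes past the threshold and an adjusted p of 0.42 with an estimated correlation, and a candidate explanation is fewer ciliated cells in the deleted isolates. Of 48 added genes of ciliated cells 47 lay below 0, with a median of -0.60 (interval -0.65 to -0.57), 9 lower adjusted over the list alone (list p = 0.14 with an estimated correlation), and Dynlrb2 had 19425 against 29951. The 24 added club cell genes had a median of -0.29, 0.31 above that of the ciliated list (interval 0.18 to 0.41). This met the condition set in advance against an equal loss of every airway cell type, but it does not decide the matter. Type II cells may express some club cell genes, which would mask a loss, and the club cell gene Scgb1a1 (160799 against 174131) lay near the top of the range. Since the isolates were pooled, a difference in yield and one in the lungs were not separated.

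Among the 10 splits of the 6 pools into 3 and 3, the genotypes gave 84 genes, the highest of the other splits gave 0, and 1 split reached 84. For lists the genotypes gave 12 and the highest of the others 13, so 2 splits gave as many. With 10 splits no share under 0.05 can be had, so neither count can be tested against chance in this way. By list, another split gave a smaller adjusted p than the genotypes for lymphocyte (5.0e-13), airway (1.2e-05) and NRF2 target lists (0.0026), and none did for cholesterol synthesis (smallest 5.9e-05), macrophage markers (1.1e-05), cytokines (4.8e-05) or fatty acid synthesis (4.0e-06). Yet of the 9 other splits 6 also called cholesterol synthesis, 6 macrophage markers, 6 cytokines and 5 fatty acid synthesis by camera. Each called between 2 and 13 lists. A small camera p with the preset correlation therefore does not by itself set the genotypes apart from other groupings. RNA integrity does not separate the groups: the mean log2 ratio of 3' to 5' control probe sets was 1.29 ± 0.03 in deleted and 1.35 ± 0.16 in control pools, which overlapped (difference -0.0578).

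A candidate explanation for the disagreeing Scd1 probe sets is that bright probe sets near the top of the range compress differences. Over 13 genes whose brightest probe set had a signal above 50000 and whose dimmer one changed, the brightest gave a median of 0.436 of the dimmer one's log2 change, against 0.67 over 120 genes between 2000 and 20000. The difference of -0.23 had a bootstrap interval from -0.52 to 0.15. Scd1, which prompted the comparison, and Fabp5 were among the 13 genes, so it is not independent of them. Genes were taken only where the dimmer probe set changed, which can lower the ratio in both classes. An interval including 0 was first set as evidence against this explanation, but this reading was changed after the result was seen, since so wide an interval excludes little, and the matter stays open.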
